A study of Homo sapiens with 3 samples.

How the data were processed

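The series held 3 single-nucleus RNA libraries of normal, untreated human salivary gland, in 1 group. The sample titles give only replicates 1 to 3. They do not say whether these came from separate donors or glands, or which gland was sampled. Each replicate is called a gland here, and n = 3 rests on that. Per the labels, 30 mg of pulverised tissue was dissociated mechanically for each library, 12000 nuclei were loaded, and libraries were made with a 3-prime droplet kit of version v3. Per the labels, the authors named Cell Ranger 2.1.1 and Seurat with genome build hg19. That release of Cell Ranger is older than the v3 chemistry. Whether the chemistry setting fitted the kit is not given in the sources used here, and all depths and counts rest on it. The role and order of these tools, the Seurat version, whether intron reads were counted and how barcodes were chosen were not given in the sources used here. The deposited matrices held raw counts, as whole-number UMI counts per gene and barcode over 32738 genes. The other deposited files held barcodes and gene names, with no measurement. No deposited cell annotation was used here, and no coordinates are given, since the reference at hand was another build.

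Depth was 4890, 2725 and 6028 barcodes with a median of 88, 151 and 161 UMIs. Shares of a single library carry exact Clopper-Pearson 95% intervals, and a count of 0 was given the limit of 3 counts. Whole-library levels were CPM (UMI counts scaled to a common library total) over all deposited barcodes, with means and SDs over 3 glands. Spread between glands was edgeR's coefficient of variation with an intercept only, after filterByExpr and TMM. Pearson correlations of log2 (CPM plus 1), across genes and not across samples, were 0.756, 0.821 and 0.815 for the 3 pairs of libraries. Genes are not independent replicates.

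Nuclei were kept at the largest gene minimum of 200, 100, 50, 30 and 20 that left at least 300 barcodes in each library, which was 50, and at most 20% mitochondrial UMIs. This kept 548, 993 and 3264 nuclei, or 11.2%, 36.4% and 54.1% of barcodes, with median depths of 187.5, 215 and 208 UMIs. The mitochondrial limit removed 4, 0 and 1. Scrublet called 18 of 4805 nuclei doublets (0.375%), which is too few for a working caller, so doublets were not removed in the adopted analysis. Each nucleus's UMIs were divided at random into 70% for clustering and naming and 30% for testing. Clustering used scanpy 1.11.5 with log counts per 10000, 2000 variable genes, scaling with a limit of 10, 30 principal components, a shared-neighbour graph of 20 neighbours over genes in at least 10 nuclei, and Leiden (leidenalg 0.10.2) at resolution 1. Mitochondrial, ribosomal protein and sex-linked genes did not enter the clustering. A cluster was named for the marker list with the most raised members (fold at least 1.5, p under 0.01), at least 3, and stayed unnamed otherwise. A cluster also stayed unnamed where another marker list held more of its 10 leading genes than the list that would have named it.

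The filter rule, the 70 and 30 percent division, the marker and gene lists, the tests, the rule for naming genes and most alternatives were set before the data were examined. Gene scaling, the neighbour graph, the minimum of nuclei per gene and the detailed naming rule were not, and were settled after cluster markers and sizes were seen and before any test result was read. In all 4 clusterings and 2 naming rules were tried. The adopted clustering was taken because it is exactly repeatable and left the serous acinar-like and acinar against duct comparisons testable. Its clusters were also judged cleaner, which was not measured. The clusterings with 15 neighbours were first tried with approximate neighbours, and their values given here come from a repeat with exact ones. In that repeat of the third clustering tried, the serous acinar-like class had 5 nuclei in replicate 1 and neither comparison could be tested. The division of barcodes by marker UMIs, with negatives matched for depth, was added after class sizes were seen.

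UMIs of each class with at least 20 nuclei in each gland were summed per gland and set against the sum of all other kept nuclei, or acinar-like against duct-like, with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood test, TMM, filterByExpr, gland as a block). Adjusted p values are Benjamini-Hochberg, with a threshold of 0.05. The plasma cell-like class, with 3 nuclei in replicate 2, was not tested. In a second design all deposited barcodes with a UMI of KLK1, of MUC19, MUC5B or BPIFB2, of IGJ or MZB1, of DCN or ABCA8, of ACTA2, MYH11 or MYLK, or of LYZ were summed per gland. Each was set against as many marker-negative barcodes of the nearest UMI number, the dividing genes left out of the test. Nuclei and barcodes were never treated as replicates. Lists with at least 3 tested members (from 18 marker and 8 function lists, with ribosomal and mitochondrial genes added) were tested with camera of limma 3.58.1 at a preset correlation of 0.01 and with an estimated one. Of 328 list genes 11 were not in the files' gene list, among them the immunoglobulin constant genes, so plasma markers rested on 6 genes.

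The tests were checked on simulated counts with the spread of each comparison, in which part of the tested genes changed. Genes changed by log2 2 upward were recovered in 10 of 10 cases for serous acinar-like, 7 of 7 for duct-like, 3 of 3 for acinar against duct and 9 of 9 for KLK1-positive sums. For changes of log2 -2 this was 7 of 10, 4 of 7, 1 of 3 and 5 of 9. Smaller changes were often missed. In the same order, log2 1 was recovered in 9 of 10, 1 of 7, 2 of 3 and 3 of 9 cases, and log2 -1 in 6 of 10, 2 of 7, 2 of 3 and 2 of 9. A gene that did not pass may thus have changed by such an amount. The fibroblast-like comparison recovered 0 of 4 at each size by edgeR, and 1 of 4 at log2 -2 by DESeq2. Its median estimates lay below the true changes. They were 0.24 and 1.11 for log2 1 and 2, and -2.46 and -3.30 for log2 -1 and -2. The highest shares of false calls were 1 of 9 in acinar against duct and 2 of 21 in KLK1-positive sums. Alternatives were DESeq2 1.42.0 and its size factors, no low-count filter, no block, each replicate left out, other gene minimums, resolutions, splits, graphs and naming rules, doublets removed, library means subtracted, all UMIs for both steps, and a 5% mitochondrial limit.

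Genes named in the text were the 10 of highest mean level, the 10 of largest range between glands among genes of at least 100 CPM and 20 UMIs, list members, and for each comparison up to 10 higher and 5 lower genes past the threshold and changed the same way in 3 glands, list members first. Sex-linked, HLA and single mitochondrial genes and clone-based identifiers were left out of naming. SAT1 in the acinar against duct comparison and MT-CO1 were named after their values were seen, and the plot of KLK1-positive barcodes shows 21 of the 23 genes that passed. Results of 2 genes named by the rule are not reported here, though counts, lists and medians include them.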

Results

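Nuclear RNA of normal, untreated human salivary gland was measured by droplet single-nucleus RNA sequencing in 3 libraries, called replicates 1 to 3. Their titles do not say whether they came from separate donors or glands, and each is called a gland here. The series held 1 group, so no comparison between conditions existed. The comparisons were between kinds of nuclei within the same glands, with the gland as the replicate (n = 3). The deposited counts covered 4890 barcodes and 502709 UMIs in replicate 1, 2725 barcodes and 448539 UMIs in replicate 2, and 6028 barcodes and 1122690 UMIs in replicate 3. The median barcode held 88, 151 and 161 UMIs from 31, 45 and 51 genes, respectively. These depths rest on counts whose chemistry setting is not given in the sources used here. At these depths 3 UMIs in a whole library corresponded to 5.97, 6.69 and 2.67 CPM, the limit that a count of 0 allowed.

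Secretory transcripts of serous saliva and a retained nuclear RNA made up most of the RNA. MALAT1 (ENSG00000251562), a long non-coding RNA kept in the nucleus, took 56.4% ± 9.10 of UMIs (SD, n = 3). The list of serous acinar markers took 17.4% ± 10.6. HTN3 (ENSG00000205649) and HTN1 (ENSG00000126550), which encode antifungal histatin peptides, averaged 38543 ± 26778 and 25947 ± 12252 CPM. STATH (ENSG00000126549), whose product statherin keeps calcium salts of saliva in solution, averaged 34892 ± 19387. CST4, CST1 and CST2, which encode salivary cystatins that inhibit cysteine proteases, averaged 16184 ± 15380, 12452 ± 13501 and 5539 ± 4877. ZG16B averaged 12093 ± 4410, SMR3B 8894 ± 6450 and PRR4, a proline-rich protein gene, 6537 ± 3515. Replicate 3 weighed heavily on several of these means. Without it, the serous list took 11.5% of UMIs, and HTN3 averaged 23601 CPM, CST4 8521.5, CST1 5065.5, CST2 3238 and SMR3B 5172. The 10 most abundant genes together took 72.5% of UMIs. The histatin, cystatin and proline-rich protein genes are close paralogs, and the division of UMIs within each family is uncertain.

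Salivary antimicrobial and immune defence genes summed to 83179 ± 41134 CPM, led by HTN3, HTN1, ZG16B and BPIFA2, and of these 18 genes 16 were detected and 12 exceeded 100 CPM. The groups below were less abundant. The 24 fluid and ion transport genes summed to 1763 ± 73.9 CPM, led by AQP5, the water channel of acinar cells. Endoplasmic reticulum protein processing genes summed to 2076 ± 365, led by XBP1 and RRBP1, and gland lineage transcription factors to 2298 ± 413, led by XBP1, EHF and ELF5. Duct markers summed to 2154 ± 621, led by KLK1, SLPI and WFDC2. Plasma cell markers summed to 861 ± 192, of which XBP1, a gene not specific to plasma cells, gave 690 ± 185, and only 1 of these 6 markers exceeded 100 CPM. Mucous acinar markers summed to 287 ± 264 (138 without replicate 1), fibroblast markers to 182 ± 80.7 and myoepithelial markers to 165 ± 56.2. Endothelial markers reached 23.5 ± 8.83, macrophage markers 48.0 ± 16.4 and T or NK markers 13.4 ± 2.05. B cell markers, at 2.96 ± 0.909, and mast cell markers, at 5.41 ± 1.64, lay about at the limit that a count of 0 allowed. Of 5 mast cell markers only 1, KIT, was detected.

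Salivary cystatins differed widely between the glands. CST4 stood at 749.9 CPM in replicate 1, against 16293 and 31509 in replicates 2 and 3, a 42.0-fold range. CST1 ranged 36.1-fold, CST2 23.8-fold and CST5 20.1-fold, each lowest in replicate 1. PRB3, a proline-rich protein gene, ranged 69.7-fold, from 6 UMIs in replicate 1 to 832 and 563 CPM in replicates 2 and 3. On 6 UMIs this range is too uncertain to rank against that of CST4. LYZ, which encodes the antibacterial enzyme lysozyme, ran the other way, at 599 CPM in replicate 1 against 105 and 95.3. The gel-forming mucin gene MUC19 ranged 11.8-fold and ODAM 11.04-fold, each highest in replicate 1 and lowest in replicate 2. HSPA1A, a heat-shock chaperone gene, had 2 and 6 UMIs in replicates 1 and 2 and 574 in replicate 3, which was 129 times the level of replicate 1 (counting interval 35.4 to 1064). FAM118A also stood highest in replicate 3, at 640 CPM against 17.9 and 24.5, a 35.7-fold range. Among the 398 genes of at least 100 CPM, the median range was 1.75-fold and 45 genes exceeded 3-fold. Over 2008 genes the edgeR coefficient of variation between glands was 0.278. Replicate 1 also had the highest MALAT1 share, 61.9% (exact Clopper-Pearson 95% interval 61.7 to 62.0), against 61.4% (61.3 to 61.6) and 45.9% (45.8 to 46.0). Its serous marker share was the lowest, 8.66% (8.58 to 8.74), against 14.3% (14.2 to 14.4) and 29.3% (29.2 to 29.4). Intervals cover counting error only.

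**Figure D1:**
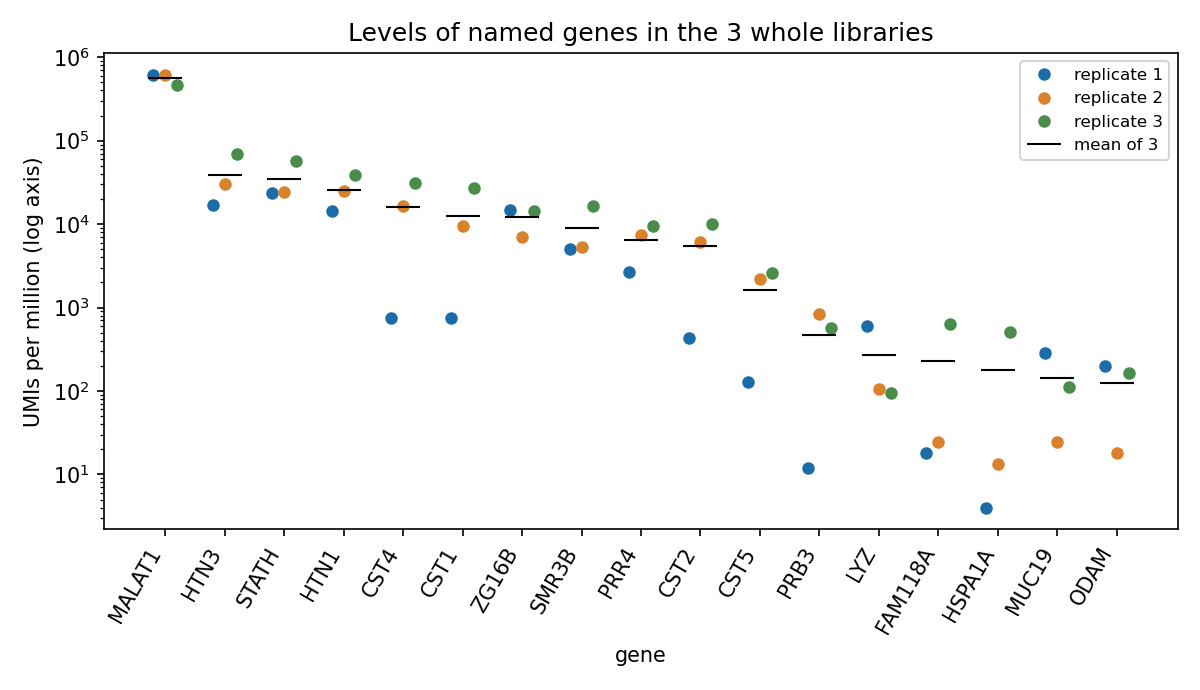
Levels of 17 named genes, on a log axis of CPM, in the 3 whole libraries; each point is 1 gland and each bar the mean of 3. The cystatin genes CST4, CST1, CST2 and CST5 were lowest in replicate 1, where LYZ was highest.

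Clustering of 4805 nuclei with at least 50 genes gave 4 named classes and a large unnamed part. Serous acinar-like nuclei made up 30.9% ± 17.6 of nuclei (SD, n = 3), and duct-like nuclei 25.4% ± 12.03. Fibroblast-like nuclei made up 2.43% ± 1.85 and plasma cell-like nuclei 0.732% ± 0.374, while 40.6% ± 11.9 stayed unnamed. The fibroblast-like share was 4.38%, 2.22% and 0.705% in replicates 1 to 3, with a mean of 1.46% without replicate 1. The serous acinar-like class held 92, 250 and 1653 nuclei of replicates 1 to 3, the duct-like class 215, 188 and 584, and the fibroblast-like class 24, 22 and 23. Raised markers named each class, among them STATH, HTN3 and CA6 for serous acinar-like, KRT7, KLK1 and WFDC2 for duct-like, and DCN, COL1A1 and C7 for fibroblast-like. MUC19 led the duct-like cluster's genes, and none of the leading genes of the serous acinar-like cluster was a serous marker. The shares were not stable: over the other clustering settings duct-like nuclei took 7.74% to 77.0% and serous acinar-like nuclei 4.001% to 40.2%.

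**Figure D2:**
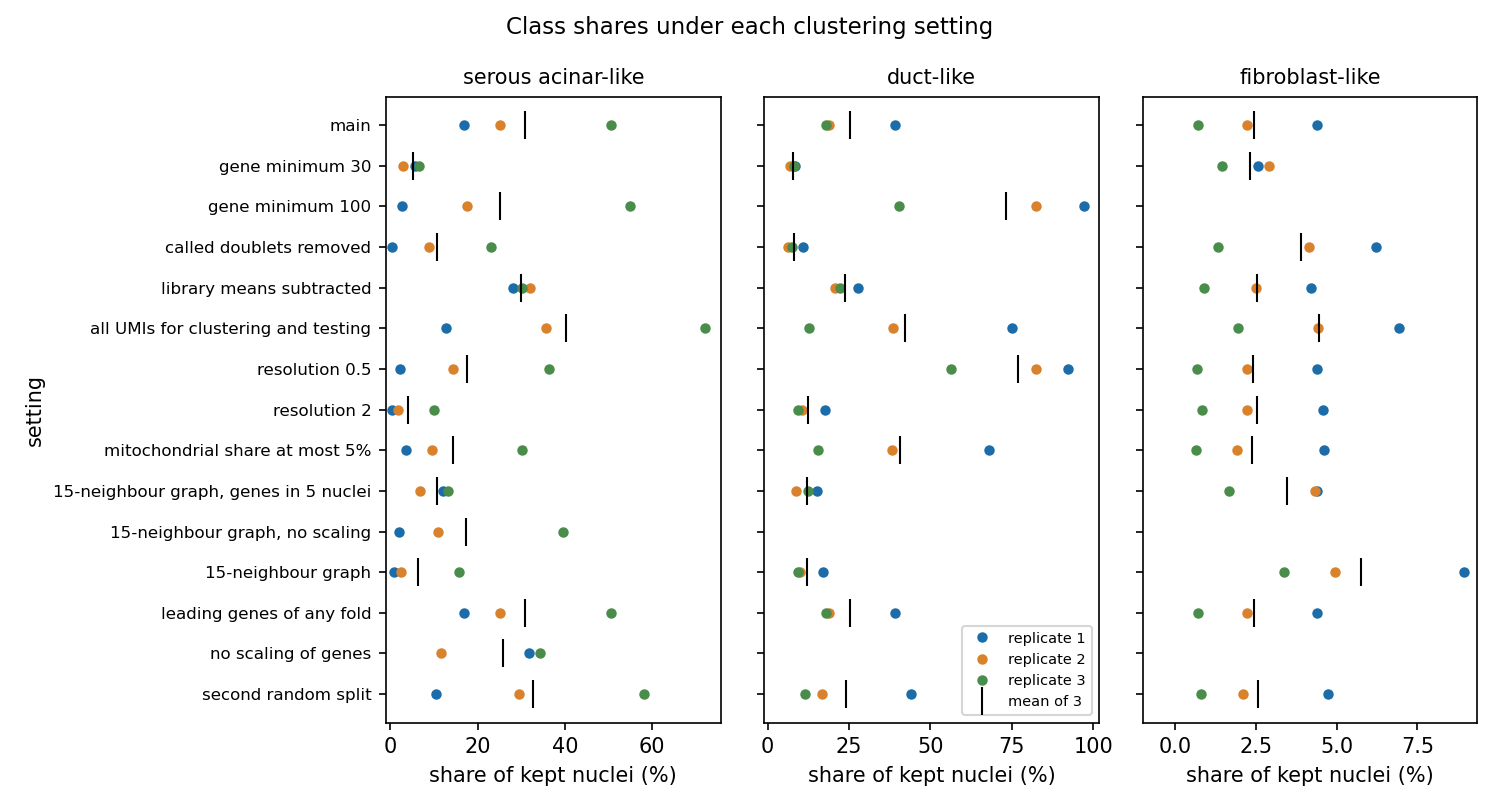
Shares of kept nuclei (percent) in 3 classes under the adopted clustering (main) and each other setting; each point is 1 gland and each bar the mean of 3, and a setting without points gave no such class. The duct-like share ran from 7.74% to 77.0%.

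Serous transcripts were found in nuclei of every class. After each nucleus was thinned to 50 UMIs, a UMI of any serous marker was seen in 99.6% ± 0.628 of serous acinar-like nuclei (n = 3). The shares were 92.0% ± 5.98 of duct-like and 91.5% ± 10.95 of fibroblast-like nuclei. Thinned STATH was seen in 76.2% ± 12.4 of serous acinar-like, 57.5% ± 11.8 of duct-like and 46.7% ± 29.1 of fibroblast-like nuclei, and unthinned in 97.9%, 86.1% and 82.6%. Without replicate 3 the thinned fibroblast-like share was 30.9%. KLK1, the kallikrein of duct cells, was seen in 8.08% ± 4.22 of duct-like nuclei, 1.69% ± 1.63 of serous acinar-like and 1.45% ± 2.51 of fibroblast-like nuclei after thinning. The fibroblast-like share rested on 1 nucleus of replicate 3, and the serous acinar-like share was 0.907% without replicate 1. Unthinned, the KLK1 shares were 24.9%, 6.24% and 4.23%, the last 2 of which were 3.93% and 2.17% without replicate 1. STATH and KLK1 had helped to name the serous acinar-like and duct-like classes. The higher share of each in its own class was thus largely set by the naming. Median depths averaged 191, 202 and 146 UMIs in duct-like, serous acinar-like and fibroblast-like nuclei.

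KLK1 and WFDC2 were lower in serous acinar-like nuclei than in the other nuclei of the same glands, which included the duct-like class that both genes had helped to define. That direction was largely set by the naming. KLK1 (ENSG00000167748) fell by 2.13 on the log2 scale (SE 0.23, adjusted p 1.4e-05) and WFDC2, a secreted protease inhibitor-like gene, by 1.71 (SE 0.34), each lower in 3 of 3 glands. MALAT1 fell by 0.55 (SE 0.09), and AHI1 by 0.88 and the splicing factor gene SRSF7 by 0.84. Serous markers took 24.5% ± 12.4 of the class's UMIs, against 15.2% ± 8.74 in unnamed and 10.5% ± 4.29 in duct-like nuclei. A fall of MALAT1 by composition therefore cannot be told apart. CST3, the cystatin C gene, rose by 0.69 (SE 0.18). Of 122 genes tested, 22 passed, 16 higher and 6 lower. Of these, 13 were serous markers that had defined the class, such as STATH, HTN3 and SMR3B, and are not results. Of 15 serous markers tested 13 rose, and of 3 duct markers 2 fell (14 and 3 adjusted over the list alone). Both list calls by camera were lost with an estimated correlation (adjusted p = 0.311 for serous markers and 0.387 for duct markers). Of 10 antimicrobial genes 4 rose and 1 fell, and the list itself did not pass (adjusted p = 0.203, and 0.643 with an estimated correlation). Among those that moved, HTN3, BPIFA2 and WFDC2 had helped to define the classes, so their direction was largely set by the naming. None of 4 gland lineage factors passed. No gene passed without replicate 3 (11 of 67 at an unadjusted p under 0.05), without the block (4 of 122) or without a low-count filter (43 of 10812), while 8 passed without replicate 2 and 15 by DESeq2. WFDC2 did not pass without replicate 1, MALAT1 did not pass with any 1 replicate left out, and AHI1, SRSF7 and CST3 each turned direction under 1 other setting.

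The regulator gene TFCP2L1 was higher and LPO was lower in duct-like nuclei than in all others. TFCP2L1, a transcription factor gene of transporting epithelia, rose by 1.69 on the log2 scale (SE 0.48, adjusted p 0.0059). ANKRD36C rose by 1.86 (SE 0.41), B2M, the light chain of class I antigen presentation, by 1.13, SAT1, a polyamine-catabolic enzyme gene, by 1.03, the histone gene H3F3B by 1.04 and CRISP3 by 0.84. LPO, which encodes the antibacterial lactoperoxidase, fell by 1.67 (SE 0.40). BPIFA2, CST2, PRB3 and HTN1 fell by 1.16, 1.16, 1.06 and 1.06, but these had helped to define the serous acinar-like class among the other nuclei, so their direction was largely set by the naming. Of 93 genes tested 19 passed, 11 higher and 8 lower, of which 3 duct markers (WFDC2, KLK1 and SLPI) had defined the class. Of 15 serous markers tested 5 fell (9 adjusted over the list alone), a list call lost with an estimated correlation (adjusted p = 0.387). The 3 duct markers' list call was lost likewise (adjusted p = 0.322). Of 10 antimicrobial genes 3 rose and 3 fell (adjusted p = 0.806 for the list), and none of 13 ribosomal protein genes passed. Mitochondrial UMIs were 0.2735% ± 0.0774 of duct-like nuclei, against 0.196% ± 0.00903 of serous acinar-like nuclei. No gene passed without replicate 1 (38 of 192 at an unadjusted p under 0.05) or without replicate 3 (4 of 50), and 2 passed without replicate 2 or without the block. DESeq2's size factors gave 29 genes, 10 higher and 19 lower, against a median shift of -0.17, DESeq2 itself gave 18, 5 higher and 13 lower, and H3F3B turned direction under 2 settings.

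Of the 16 genes that passed in fibroblast-like nuclei against all others, 4 had helped to define the class and 12 had not. LPO, CA6, a secreted carbonic anhydrase gene, and C1orf63 had 0 UMIs among the 3220 tested UMIs of the class, which made LPO at least 1.21-fold, CA6 at least 1.48-fold and C1orf63 at least 1.62-fold lower, over the 3 glands together. LPO and C1orf63 did not pass without replicate 1 or without replicate 3. HTN1 fell by 2.63 on the log2 scale (SE 0.76, adjusted p 0.0093) and STATH by 2.01 (SE 0.71, adjusted p 0.026), each in 3 of 3 glands. These sizes rest on TMM scaling, with factors of at least 1.17 for fibroblast-like sums and at most 0.82 for the other sums. Simulated changes of log2 -2 in this comparison had a median estimate of -3.30, so these falls may be overstated. Over the 3 glands together STATH had 60 of 3220 tested UMIs, against 16135 of 328827 in the other nuclei. HTN1 had 29, against 11089. HTN1, STATH and CA6 had helped to define the serous acinar-like class among the other nuclei, so their direction was largely set by the naming. SPARCL1, a matricellular protein gene, rose by 3.46 (SE 1.20) on 4 UMIs, and STEAP4, a metalloreductase gene, on 3 UMIs, at 14.6 times the other nuclei's rate (counting interval 2.79 to 48.9). With any 1 replicate left out, SPARCL1 had too few UMIs to be tested, and STEAP4 did not pass or was not tested. Of 59 genes tested 16 passed, 8 higher and 8 lower. APOD, CFD, IGFBP7 and MT2A, which led the cluster, were among those higher and are not results. Of 14 serous markers tested 4 fell and none rose (7 fell adjusted over the list alone), a list call lost with an estimated correlation (adjusted p = 0.387). The antimicrobial list, with 2 of 6 lower, did not pass (adjusted p = 0.0828, and 0.627 with an estimated correlation). Mitochondrial UMIs were 1.25% ± 0.648 of these nuclei, against 0.196% ± 0.00903 in serous acinar-like nuclei. The median log2 fold change over the 59 genes was -1.02, DESeq2's size factors moved it by a further -1.004 to 39 genes, 4 higher and 35 lower, and DESeq2 gave 32, 5 higher and 27 lower. The class had 22 to 24 nuclei per gland, 9 genes passed without replicate 3, and STEAP4 turned direction without a low-count filter.

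Acini secrete primary saliva and ducts modify it, and the direct comparison of serous acinar-like with duct-like nuclei gave few genes beyond the markers. A mucous acinar marker was seen unthinned in 7.6% of duct-like and 1.996% of serous acinar-like nuclei. The duct-like side thus need not hold duct nuclei alone. MALAT1 fell by 1.10 on the log2 scale (SE 0.31, adjusted p 0.0053) and NEAT1, another retained nuclear RNA, by 0.76 (SE 0.27), in acinar-like relative to duct-like nuclei. These changes rest on TMM scaling, with factors of 1.29, 1.15 and 1.44 for acinar-like and 0.878, 0.575 and 0.926 for duct-like sums. As a share of all UMIs MALAT1 differed less, at 54.25%, 53.2% and 37.7% against 58.9%, 63.2% and 55.1% in replicates 1 to 3. Serous markers took 24.5% ± 12.4 against 10.5% ± 4.29, so a fall by composition cannot be told apart. SAT1, picked out after its value was seen, fell by 1.92 (SE 0.45). Of 40 genes tested 9 passed, 3 higher and 6 lower, and the other 6 were class markers (SMR3B, HTN1, HTN3, KLK1, WFDC2 and SLPI). Of 14 serous markers 3 rose (4 adjusted over the list alone) and of 3 duct markers 3 fell, and both list calls were lost with an estimated correlation (adjusted p = 0.311 and 0.387). The antimicrobial list, with 2 higher and 2 lower of 9, did not pass (adjusted p = 0.832). No gene passed without replicate 3 (10 of 36 at an unadjusted p under 0.05), 23 passed without replicate 1, and 13 by DESeq2. DESeq2's size factors shifted the median by 0.35 and gave 9 higher and 5 lower. MALAT1 did not pass with any 1 replicate left out, and NEAT1 turned direction under 3 settings, among them without replicate 1.

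Barcodes with a KLK1 UMI carried more HSD11B2, TFCP2L1, ATP6V1C2 and ATP1B1 transcripts than barcodes of the same depth without one. HSD11B2 (ENSG00000176387), the enzyme that shields the mineralocorticoid receptor from cortisol, rose by 3.97 on the log2 scale (SE 0.63, adjusted p 4.2e-08). TFCP2L1 (ENSG00000115112) rose by 3.29 (SE 0.34), ATP6V1C2, a proton pump subunit gene, by 3.75 (SE 0.55), and ATP1B1, a cation pump subunit gene, by 2.53 (SE 0.32). WFDC2 rose by 1.53, the iron storage gene FTH1 by 1.53, B2M by 1.24 and GSTK1 by 1.03. LPO fell by 1.47 (SE 0.31) and STATH by 0.89 (SE 0.32), as did PDE4D, PDK4 and TECPR1, by 1.79, 1.68 and 1.59. Each gene named moved the same way in 3 of 3 glands. This division, without clustering, was chosen after the data were seen, with 1 KLK1-negative barcode of nearest depth for each of the 300, 77 and 435 positive ones. Of 114 genes tested 23 passed, 14 higher and 9 lower. Of 3 transport genes tested 2 rose and AQP5 did not (log2 -0.56, adjusted p 0.184), of 3 duct markers 2 rose and SLPI did not (log2 0.06, adjusted p 0.933), and of 15 serous markers 2 fell, with the same counts adjusted over the list alone. All 3 list calls were lost with an estimated correlation (adjusted p = 0.513). Among ribosomal protein genes 2 of 16 rose, among them RPL3 by 0.88, and MT-CO1, named after its value was seen, rose by 1.11. The mitochondrial list did not pass (adjusted p = 0.0564), nor did the antimicrobial list (0.13). Without replicate 3, 14 genes passed, without replicate 2, 56, by DESeq2 11, and without the block 5, all of them higher. None of the lower genes passed without the block, and LPO also did not pass without replicate 1 or without replicate 3.

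**Figure D3:**
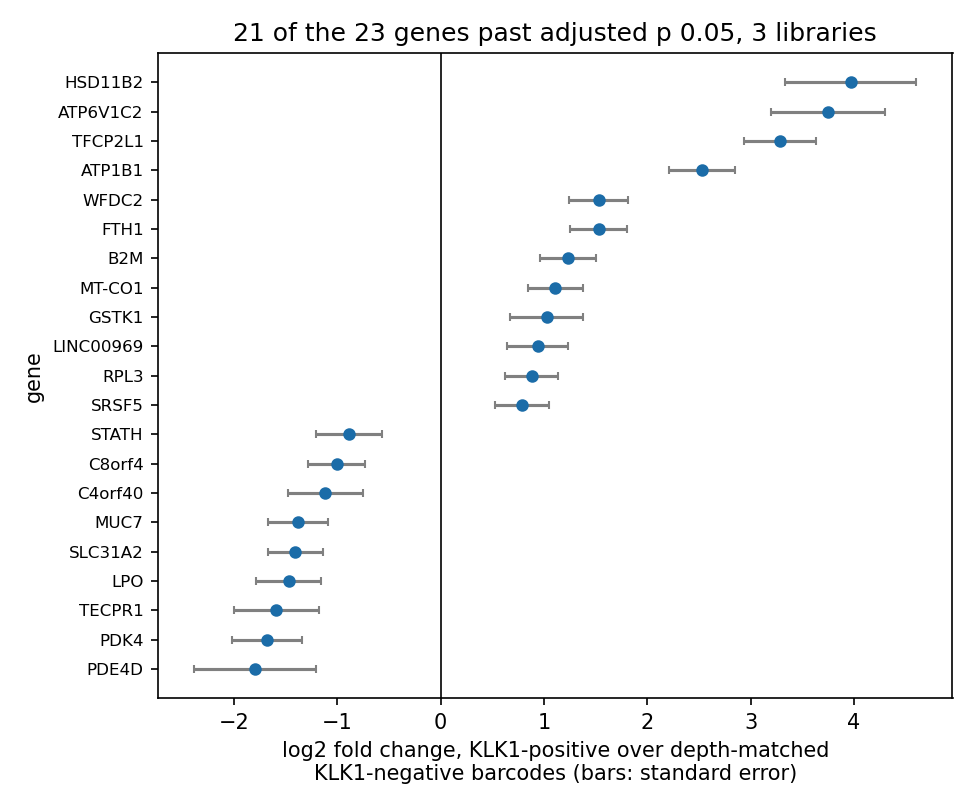
Log2 fold change of 21 of the 23 genes past adjusted p 0.05 in KLK1-positive over depth-matched KLK1-negative barcodes of 3 glands; points are edgeR estimates and bars standard errors. HSD11B2, ATP6V1C2 and TFCP2L1 lay farthest to the right, and PDE4D, PDK4 and TECPR1 farthest to the left.

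The other marker divisions, also chosen after the data were seen, gave few genes. Barcodes with ACTA2, MYH11 or MYLK, contractile genes of smooth muscle and myoepithelial cells, carried more MIR205HG (log2 4.89, SE 0.79), CALD1, an actin-binding gene (4.53, SE 0.89), and CST3 (3.25, SE 0.67). MIR205HG had 3 UMIs on the negative side, a ratio of 25.3 (counting interval 8.34 to 125), and CALD1 had 2, a ratio of 19.97 (5.18 to 171). Of 19 genes tested these 3 passed, 1 without replicate 1 and 0 without replicate 3, where 3 passed at an unadjusted p under 0.05. Barcodes with a UMI of MUC19, MUC5B or BPIFB2 held less KLK1 (-2.47, SE 0.61) and more NEAT1 (1.13, SE 0.34). These were 2 of 44 genes. None passed by DESeq2 (4 at an unadjusted p under 0.05) or without replicate 2 (1), 1 passed without replicate 3 and 5 passed without replicate 1, and NEAT1 turned direction under 2 settings. Their serous and antimicrobial list calls were both lost with an estimated correlation (adjusted p = 0.513). No gene passed by edgeR in barcodes with IGJ or MZB1 (0 of 15 at an unadjusted p under 0.05, 0 by DESeq2, 1 without replicate 2). None passed in those with DCN or ABCA8 (1 of 30 unadjusted, 0 by DESeq2, 1 without replicate 3). None passed in those with LYZ (7 of 42 unadjusted, 3 by DESeq2, 12 without replicate 2, 3 without replicate 3).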

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

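The tests on paralogs, on less secretory RNA of every kind, on doublets, and both tests on KLK1-positive barcodes were chosen only after the result was seen.

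Barcodes left out by the gene minimum or the mitochondrial limit took no part in the class comparisons and still held cell type transcripts. Among these 8838 barcodes, KLK1 had a UMI in 3.78% (5.04%, 1.44% and 3.26% in replicates 1 to 3) and DCN, the fibroblast proteoglycan gene, in 0.362% (0.368%, 0.462% and 0.289%). The mucin gene MUC19 had a UMI in 1.01% (1.54%, 0.173% and 0.687%), and in 0.489% without replicate 1. IGJ, the immunoglobulin joining chain gene, had one in 0.577% (0.207%, 0.289% and 1.34%), in 0.934% without replicate 1 and in 0.230% without replicate 3. Free RNA and whole nuclei of few UMIs were not separated for these shares, and a count of 0 would have allowed 0.0339%.

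Salivary cystatin transcripts were low in replicate 1, with CST1, CST2, CST3, CST4 and CST5 together at 2435 CPM against 34363 and 72298. An uneven division of UMIs among the paralogs is argued against, since their sum still lay at log2 -3.82 relative to the lower of the other glands, and so are shallow barcodes, since the ratio was -3.70 past the filter. Less secretory RNA of every kind in replicate 1 stays open: the median log2 ratio of the cystatins minus that of the other 14 serous markers was -3.36, within 2 SD of these (SD 1.87). The median log2 ratio of these 14 was -1.06. Only 1 of them, LYZ, stood above both other replicates beyond counting error, at 599 CPM against 105 and 95.3. ZG16B and ODAM were also highest there, at 14748 against 7003 and 14528, and 197 against 17.8 and 163. Neither exceeded replicate 3 beyond counting error. No biological explanation was tested, since the design names no difference between the glands.

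Secretory transcripts were seen in fibroblast-like nuclei. Doublets of fibroblast and serous nuclei stay open. The median UMI count of fibroblast-like nuclei was at most 0.803 of that of all kept nuclei, but these had all passed the gene minimum. The fibroblast-like medians were 150.5, 136.5 and 151 UMIs, against 88, 151 and 161 over all deposited barcodes of replicates 1 to 3. Doublets of 2 shallow nuclei could reach such depths, so depth cannot decide. Free RNA of 1 source stays open. The proportions of 8 secretory genes differed from those of the other nuclei in replicates 2 and 3 (Monte Carlo chi-square, unadjusted p 0.302, 0.0057 and 0.0308 in replicates 1 to 3, lowest adjusted p 0.0171), but those nuclei hold serous RNA of their own, so their proportions are not those of free RNA. No biological explanation was tested, and nuclei wrongly placed in the class stay open.

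Several duct and transport genes were raised in KLK1-positive barcodes: of 6 tested members 4 rose, with a median log2 fold change of 1.78 (median SE 0.30) over the 6, while AQP5 (-0.56, SE 0.31) and SLPI (0.06, SE 0.30) did not pass. Both list calls were lost with an estimated correlation (adjusted p = 0.513). Cytoplasmic RNA carried with the nuclei stays open too. The 16 ribosomal protein genes had a median of 0.25 (SD 0.34), but such genes are transcribed in each kind of cell. Cytoplasm of duct cells could thus raise duct genes with little change in them, so their median decides nothing. KLK1 picked up as free RNA stays open, since the median was taken over the genes that make up the pattern and decides nothing. RPL3 and MT-CO1 rose, and no biological explanation was tested.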

How the results depend on the processing

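Tests chosen only after the data were seen were those under the second random split, no scaling of genes, the 15-neighbour graphs, leading genes of any fold, and each value for marker-positive barcodes. Genes past the threshold numbered 19 in duct-like, 16 in fibroblast-like, 22 in serous acinar-like, 9 in acinar against duct, 23 in KLK1-positive, 2 in mucin-positive, 0 in IGJ- or MZB1-positive, 0 in DCN- or ABCA8-positive, 3 in contractile-gene-positive and 0 in LYZ-positive sums. With each replicate left out in turn the counts ran 0 to 2 (duct-like), 9 to 18 (fibroblast-like), 0 to 17 (serous acinar-like), 0 to 23 (acinar against duct), 14 to 56 (KLK1-positive), 0 to 5 (mucin-positive), 0 to 1 (IGJ- or MZB1-positive), 0 to 1 (DCN- or ABCA8-positive), 0 to 3 (contractile-gene-positive) and 0 to 12 (LYZ-positive). With DESeq2's size factors, the count became 29 (duct-like), 39 (fibroblast-like), 14 (acinar against duct), 0 (mucin-positive, 4 unadjusted) and 10 (LYZ-positive). Without a low-count filter, the count became 29 (duct-like), 73 (fibroblast-like), 0 (serous acinar-like, 43 unadjusted), 0 (acinar against duct, 56 unadjusted), 5 (mucin-positive), 1 (IGJ- or MZB1-positive), 3 (DCN- or ABCA8-positive) and 1 (LYZ-positive). Of the 29 duct-like genes 3 were higher and 26 lower, and the 73 fibroblast-like genes were all lower. Without the gland as a block, the count became 2 (duct-like), 0 (serous acinar-like, 4 unadjusted), 1 (acinar against duct), 5 (KLK1-positive) and 0 (mucin-positive, 1 unadjusted). By DESeq2, the count became 32 (fibroblast-like), 11 (KLK1-positive), 0 (mucin-positive, 4 unadjusted) and 3 (LYZ-positive). At a gene minimum of 30, the count became 8 (serous acinar-like) and 2 (acinar against duct). With library means subtracted, the count became 36 (duct-like) and 15 (acinar against duct). With all UMIs for both clustering and testing, the count became 67 (fibroblast-like), 46 (serous acinar-like) and 33 (acinar against duct). Duct-like sums then gave 20 genes, of which 5 were among the 19 of the adopted analysis with the same direction. At a gene minimum of 30, duct-like sums gave 17 with 8 shared, and serous acinar-like sums shared 1 of 22. With library means subtracted, 17 of the 19 and 16 of the 22 were shared. At resolution 0.5, the count became 2 (duct-like). At resolution 2, the count became 12 (duct-like). At a mitochondrial limit of 5%, the count became 5 (duct-like). With a 15-neighbour graph and genes in 5 nuclei, the count became 4 (fibroblast-like), 1 (serous acinar-like) and 0 (acinar against duct, 2 unadjusted). With a 15-neighbour graph, the count became 12 (duct-like) and 7 (fibroblast-like). Without scaling of genes, the count became 13 (serous acinar-like). With a second random split, the count became 22 (acinar against duct). With barcodes past the filter only, the count became 53 (KLK1-positive), 2 (IGJ- or MZB1-positive), 9 (DCN- or ABCA8-positive) and 23 (contractile-gene-positive). Against all marker-negative barcodes, not matched for depth, the count became 115 (KLK1-positive), 14 (mucin-positive), 6 (IGJ- or MZB1-positive), 34 (DCN- or ABCA8-positive), 74 (contractile-gene-positive) and 1 (LYZ-positive). The cause was not tested, except that fewer libraries were used where a replicate was left out and more genes were tested without a low-count filter.

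Class shares moved by more than 1 SD. The serous acinar-like share, 30.9%, became 5.10% with a gene minimum of 30, 10.8% with doublets removed, 4.001% with resolution 2, 10.7% with the 15-neighbour graph with genes in 5 nuclei and 6.42% with the 15-neighbour graph. The duct-like share, 25.4%, became 7.74% with a gene minimum of 30, 73.4% with a gene minimum of 100, 8.18% with doublets removed, 42.1% with all UMIs for both steps, 77.0% with resolution 0.5, 12.5% with resolution 2, 40.6% with a mitochondrial limit of 5%, 12.2% with the 15-neighbour graph with genes in 5 nuclei and 12.1% with the 15-neighbour graph. The fibroblast-like share, 2.43%, became 4.44% with all UMIs for both steps and 5.75% with the 15-neighbour graph. The plasma cell-like share, 0.732%, became 11.7% with library means subtracted, 1.16% with all UMIs for both steps and 2.69% with the 15-neighbour graph. The unnamed share, 40.6%, became 82.2% with a gene minimum of 30, 1.52% with a gene minimum of 100, 77.2% with doublets removed, 10.7% with all UMIs for both steps, 2.92% with resolution 0.5, 80.9% with resolution 2, 70.6% with the 15-neighbour graph with genes in 5 nuclei, 72.3% with that graph without scaling, 71.3% with the 15-neighbour graph and 74.1% with no scaling. A class of 1 name need not hold the same nuclei under each setting. Doublet removal took out only 17, 1 and 0 nuclei of replicates 1 to 3. Even so, the serous acinar-like share of replicate 3 went from 50.6% to 23.2%. For each set of kept nuclei the UMIs were divided and the nuclei clustered anew, so such shifts cannot be read as effects of the nuclei removed. 

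These log2 fold changes turned direction. In serous acinar-like sums with the 15-neighbour graph and genes in 5 nuclei these were HTN3 from 0.69 to -0.0331, CST3 from 0.69 to -0.00263, CST2 from 0.58 to -0.0385, CA6 from 0.53 to -0.18 and PRH2 from 0.49 to -0.0766. There were also AHI1 from -0.88 to 0.0788 (a gene minimum of 30) and SRSF7 from -0.84 to 0.20 (a second random split). In duct-like sums these were H3F3B from 1.04 to -0.17 (a gene minimum of 30) and -0.17 (a mitochondrial limit of 5%). In fibroblast-like sums these were STEAP4 from 3.51 to -0.0794 (no low-count filter). In acinar against duct sums these were NEAT1 from -0.76 to 0.0284 (all UMIs for both steps), 0.23 (no low-count filter) and 0.11 (replicate 1 left out, with -0.44 as the lowest over the replicates left out). In mucin-positive sums these were NEAT1 from 1.13 to -0.0705 (barcodes past the filter) and -0.18 (unmatched negatives). With an estimated correlation each of the 12 list calls was lost, at an adjusted p of 0.311, 0.322, 0.387 and 0.513.

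Over the other settings, values of named genes kept their direction and their side of the threshold, or kept direction only, in 95 and 102 cases (serous acinar-like), 116 and 127 cases (duct-like), 121 and 29 cases (fibroblast-like), 48 and 47 cases (acinar against duct), 87 and 41 cases (KLK1-positive), 4 and 12 cases (mucin-positive) and 22 and 5 cases (contractile-gene-positive). HSD11B2, TFCP2L1 and ATP1B1 in KLK1-positive sums passed under each of 9 alternatives. Whole-library levels moved by less than 1 SD in 71 cases and by more in 13. With barcodes past the filter only, the median UMI and gene numbers were 203.5 and 60.3 in place of 133 and 42.3. The coefficient of variation between glands, 0.278, was 0.308 without a low-count filter and ran from 0.240 to 0.287 with a replicate left out. Without thinning, a mucous marker was seen in 1.996% of serous acinar-like (thinned 0.596%), 7.6% of duct-like (thinned 2.37%), 1.39% of fibroblast-like (thinned 0%) and 2.01% of unnamed (thinned 0.749%) nuclei. In replicates 2 and 3 alone the thinned serous acinar-like share was 0.351%, and the unthinned fibroblast-like share rested on 1 nucleus of replicate 1. STATH was seen unthinned in 97.9% of serous acinar-like, 86.1% of duct-like, 82.6% of fibroblast-like and 93% of unnamed nuclei (unnamed thinned 64.7%), and any serous marker in 98.7% of duct-like nuclei. At a gene minimum of 100 no comparison had enough nuclei on both sides, since the duct-like class had at least 28 nuclei per gland and the other nuclei as few as 1. The serous acinar-like and acinar against duct comparisons could not be fitted with doublets removed, at either other resolution, at a mitochondrial limit of 5% or with the 15-neighbour graph. The fibroblast-like one could not be fitted at that limit, and no duct-like or fibroblast-like class was found without scaling. With the 15-neighbour graph without scaling, the serous acinar-like class had 11 nuclei in replicate 1 and was not tested. Depth limited the tests to genes of many UMIs, 40 to 122 in the class comparisons.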

Other observations

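The tests on marker-positive barcodes reported here were chosen only after the data were seen, and the splits for the class comparisons were set earlier.

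Other gene groups were measured in the whole libraries. Immediate early and stress genes summed to 1414 ± 55.2 CPM (SD, n = 3), led by DUSP1 and JUN, although HSPA1A alone ranged widely. Nuclear-encoded genes of mitochondrial energy metabolism summed to 1220 ± 314, led by COX5B, a subunit of cytochrome c oxidase. The list set for mucin type O-glycosylation summed to 322 ± 58.6, led by FUT8 and FUT2, fucosyltransferase genes. FUT8 acts on N-glycans, so the sum is not one of O-glycosylation genes alone. Retained nuclear transcripts, mostly MALAT1, took 56.7% ± 9.24 of UMIs.

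Markers of rarer cell types were few. Ionocyte markers summed to 87.2 ± 13.1 CPM, led by CFTR, the chloride channel, and basal duct markers to 54.6 ± 25.8, led by KRT14. Mural markers reached 85.2 ± 36.2, led by ACTA2. ACTA2 and MYH11 are also in the myoepithelial list, which shares KRT14 with the basal duct list. These sums thus count some of the same UMIs and do not part the cell types. Schwann cell markers reached 19.9 ± 2.21, adipocyte markers 14.2 ± 1.47, skeletal muscle markers 34.2 ± 34.2 (14.5 without replicate 1) and erythroid markers 4.74 ± 2.97 (3.10 without replicate 3), the last at about the limit that a count of 0 allows. Ribosomal protein genes took 1.33% ± 0.601 and mitochondrial genes 0.186% ± 0.0457 of UMIs.

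Barcodes with a KLK1 UMI were 6.13% (exact 95% interval 5.48 to 6.84), 2.83% (2.24 to 3.52) and 7.22% (6.58 to 7.90) of replicates 1 to 3. Barcodes with a LYZ UMI were 5.21% (4.61 to 5.88), 1.505% (1.08 to 2.04) and 1.24% (0.98 to 1.56), at median depths of 95, 119 and 151 UMIs.

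Each comparison was repeated on the 10 splits of its 6 sums into groups of 3, which are too few for a share under 0.05. The real and the highest other counts were 22 and 1 in serous acinar-like, 19 and 0 in duct-like, 16 and 0 in fibroblast-like and 9 and 3 in acinar against duct. They were 23 and 0 in KLK1-positive, 2 and 0 in mucin-positive, 3 and 1 in contractile-gene-positive, 0 and 1 in IGJ- or MZB1-positive, 0 and 1 in DCN- or ABCA8-positive and 0 and 0 in LYZ-positive sums. The sums are paired by gland, and 4 of the splits part both sums of each gland, as the real one does, while the other 6 keep both sums of 2 glands together. Among the splits that part each pair, the highest other count was 1 in acinar against duct and in DCN- or ABCA8-positive sums, and 0 in the 8 other comparisons. In the KLK1-positive, duct-like, fibroblast-like, serous acinar-like, acinar against duct, mucin-positive and contractile-gene-positive sums 1 split, the real one, gave as many genes. In the 3 others all 10 splits did, since the real count was 0.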
